A study of Homo sapiens with 18 samples.

How the data were processed

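Bulk RNA sequencing of H9 human embryonic stem cells was analysed from the files that the authors deposited, 1 per library for 18 libraries. Per the file headers, the authors made each file with rpkmforgenes, using uniquely mapped reads and RefSeq gene models. Each deposited file gives for 21846 gene entries an RPKM (reads scaled to transcript length and library size) and a whole-number read count. According to the labels, the reads were single reads from a HiSeq2500 and were processed with bcl2fastq, CASAVA 1.8.2, Trimmomatic 0.3.3, TopHat2 2.0.14 and Bowtie2 2.2.5 against hg19. The headers show no strand option, so reads from overlapping and antisense genes were counted together. The files join 1959 sets of overlapping genes into single entries, which hold 20.6% of the counts, and these are printed with a plus sign between the symbols. In 270 entries a name used by an earlier entry is repeated. Genes are named by the symbols of the files, which pair each with its RefSeq transcripts and give no positions. Positions and neighbours, where used, were found by gene name in the annotation of GRCh38.p14, and no coordinate is given because the counts rest on another assembly.

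The counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr by group, quasi-likelihood test with robust=TRUE) in 1 fit of 6 group means over the 18 libraries, with 12 residual degrees of freedom and a median biological coefficient of variation of 0.0611. Of the 21846 entries, 1605 had 0 counts in all libraries and 15645 passed the filter and were tested. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its log2 fold change was at least 1 in size, and rose, fell and changed are used only for called genes and for lists past their test. Fold changes are log2 values, and the ± after a fold is its size divided by the square root of the test's F. This ± stands in for a standard error and is too small where 1 side has few counts. SPIC, with 6 counts in primed cells, had ± 0.16 in AICAR against primed but ± 1.20 in Primed2 against Primed1. Levels are mean CPM (counts scaled by edgeR to TMM-adjusted library size) with SD over 3 libraries. The primed reference is the mean of the log2 levels of Primed1 and Primed2, because the labels tie neither primed group to any treated group, so where the primed groups differ the fold is not the ratio of pooled counts. Where one side had 0 counts the fold is a bound from a floor of 3 counts over the group, and with 1 to 3 counts the ratio of pooled counts is given with its 95% counting interval. Intervals and floors cover counting error only.

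Before the data were examined, 7 comparisons, 26 gene lists, the alternatives and the rule for naming genes were fixed. The rule names NANOG, KLF2, POU5F1, SOX2, KLF17, DPPA3, DPPA5, TFCP2L1, DNMT3L, DNMT3B, ZIC2, OTX2, PRKAA1 and PRKAA2 in each comparison with primed cells. It adds up to 2 members per list with the largest change that held against each primed group (and for each AICAR group), and over all genes the 5 largest rises and the 5 largest falls of this kind with at least 20 counts in every library of the higher side. In the other 4 comparisons it names the 5 largest rises and the 5 largest falls with that many counts. Where 1 group of a comparison had 0 counts, pooled counts and their ratio, scaled by library size, are given in place of a fitted change. Some genes that the rule names, and some called list members, are not reported here. Members of a list may be named where the list is described, and members listed for a count of 5 or fewer were named after their values were seen. The lists were naive pluripotency, primed pluripotency, core pluripotency, DNA methylation machinery, AMPK subunits and regulators, purine synthesis and AICAR metabolism, complex I subunits, other oxidative phosphorylation subunits, glycolysis, sterol and fatty acid synthesis, ERK feedback targets, Wnt and beta-catenin targets, and STAT3 targets. The others were trophoblast, amnion, primitive endoderm, mesendoderm, neuroectoderm, fibroblast (feeder layer), cleavage-stage, methylation-silenced germline genes, imprinted genes, p53 targets, YAP and TEAD targets, S and G2/M phase, and endoplasmic reticulum and integrated stress.

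Each list was tested with camera from limma 3.58.1 (inter-gene correlation preset at 0.01, two-sided, adjusted over the 26 lists within a comparison), and an estimated correlation was an alternative. The limma test fry, which asks whether a list's genes move on balance one way without comparing them with other genes, was run beside it. List counts were also adjusted over the list alone. The shared response of 2 comparisons was measured by genes called in both, by the overlap that independent calls would give, and by the correlation and covariance of log2 fold changes across genes, beside 20 simulations of all libraries in which the reset groups were unchanged and the primed groups kept their levels. Alternatives were relative log expression (RLE) size factors, library totals alone, DESeq2 1.42.0, limma on log2(RPKM + 1), no low-count filter, a CPM of 1 in 3 libraries, no fold threshold, a replicate block, only the groups compared, group as a random block, each primed or AICAR group alone, split primed references, thinning every library to the smallest total and leaving out each library in turn. Library totals alone, thinning and the list tests for AICAR2 against AICAR1 and Primed2 against Primed1 were added after the data were seen.

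The test was checked on simulated data with 50 changed genes at each fold. For AICAR against primed, with 14882 genes tested, 38% of the genes changed 2-fold and 100% of those changed 3-fold were called. For AICAR2 against AICAR1, with 13939 genes tested, 48% and 96% were called, and 3 unchanged genes were called. All 7 moved lists were found and 0 of 140 unmoved lists were called by camera in the simulated data. Genes were drawn independently there, so this does not check false calls for lists whose genes vary together. Replicates of AICAR2 differed by little more than counting noise (chi-square per degree of freedom from 1.53), against up to 36.8 in 5iLA, and the labels do not say whether replicates are independent cultures. XIST and genes on chromosome Y were left out of all named results.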

Results

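RNA was sequenced from H9 cells, a human embryonic stem cell line, in 18 libraries of 6 groups with 3 libraries each. Primed1 and Primed2 were labelled as primed, the usual state of human embryonic stem cells, and as untreated. AICAR1 and AICAR2 were kept for 21 days with AICAR, a nucleoside that cells turn into an activator of the energy-sensing kinase AMPK (1 mM for 2 weeks, then 0.5 mM). A protocol text, which names AICAR but is the same on every sample, gives a medium that also held inhibitors of MEK, GSK3 and protein kinase C, the cytokine LIF and a ROCK inhibitor, followed by puromycin at 1 µg/mL, on mouse feeder cells. It was taken to apply to the AICAR groups, and which parts apply to the other groups is not given, so each comparison with primed cells is of a treatment plus its medium. NK2 cells were labelled as carrying induced NANOG and KLF2, transcription factors of pluripotency, for 14 days. 5iLA cells were kept for 12 days with inhibitors of MEK, GSK3, ROCK, BRAF and SRC plus activin and LIF. The AICAR, NK2 and 5iLA groups are called reset groups, after the aim of the cultures, which per the series title was naive pluripotency.

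Total counts of the 3 libraries were 21145597, 31806700 and 24607089 in Primed1, and 18403675, 25693321 and 27591127 in Primed2. They were 21776149, 25704486 and 21027913 in AICAR1, and 18937403, 17661243 and 19795807 in AICAR2. The NK2 libraries held 19678169, 14448319 and 18584418 counts, and the 5iLA libraries 18125621, 14468070 and 17546664. A floor of 3 counts in a library was 0.0943 to 0.208 CPM. On average 14713 (SD 321) genes had at least 10 counts in Primed1, 14842 (SD 295) in Primed2, 13696 (SD 131) in AICAR1, 13261 (SD 115) in AICAR2, 13309 (SD 230) in NK2 and 13283 (SD 118) in 5iLA. Pearson correlations of log2 CPM across genes, which are not independent replicates, were at least 0.989 within groups, 0.980 to 0.982 between AICAR1 and AICAR2, 0.981 to 0.984 between AICAR1 and NK2, 0.9657 to 0.9695 between AICAR2 and NK2, 0.974 to 0.979 between AICAR1 and 5iLA, 0.968 to 0.974 between AICAR2 and 5iLA, 0.912 to 0.929 between Primed1 and Primed2, and 0.750 to 0.806 between primed and reset libraries. The first principal component held 77.4% of the variance and the second held 9.34%.

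The induced genes were measured in every group first. NANOG stood at 181 ± 11.3 CPM (SD, n = 3) in Primed1, 31.3 ± 12.5 in Primed2, 247 ± 6.95 in AICAR1, 312 ± 2.61 in AICAR2, 160 ± 2.88 in NK2 and 203 ± 3.19 in 5iLA. KLF2 stood at 2.71 ± 0.239 CPM in Primed1, 1.77 ± 0.575 in Primed2, 16.4 ± 0.229 in AICAR1, 18 ± 1.02 in AICAR2, 10.4 ± 0.906 in NK2 and 16.9 ± 1.10 in 5iLA. Neither gene was higher in NK2, the group labelled with induction, than in the other reset groups, and NANOG was not higher there than in Primed1. Induction is thus known from the labels only, and the files do not tell reads of a transgene from those of the natural gene.

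The first comparison, AICAR against primed (6 libraries against 6), asks how cells kept with AICAR and its medium differ from primed cells. Naive pluripotency genes, active in the epiblast before implantation, rose and primed genes fell. DNMT3L, a cofactor of DNA methyltransferases, rose by 11.17 ± 0.05 on the log2 scale, from 0.406 CPM in Primed1 and 0.934 in Primed2 to 1226 in AICAR1 and 1698 in AICAR2. DPPA5, an RNA-binding protein of pluripotent cells, rose by 10.10 ± 0.05 (from 1.04 and 0.389 to 636 and 758 CPM), the transcription factor KLF17 by 9.78 ± 0.11, DPPA3 by 7.80 ± 0.05 and TFCP2L1 by 6.08 ± 0.07. PTPRZ1, a receptor phosphatase, fell from 254 and 239 CPM to 0 counts in AICAR1 and 11 in AICAR2, a ratio of 2993. ZIC2 fell by 5.84 ± 0.11, OTX2 by 2.40 ± 0.07 and SOX2 by 2.33 ± 0.04.

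In AICAR against primed 7072 genes were called, 2701 higher and 4371 lower. All 22 measured naive genes rose (median 7.40, adjusted p = 3.56e-12), led by HORMAD1 (4 counts to 9592, a ratio of 2865) and KHDC1L at 11.30 ± 0.07. Of 23 primed genes 22 fell (median -5.84, adjusted p = 1.78e-09), and SALL3 was at -0.82 ± 0.05. THY1 had 2 counts over the 6 AICAR libraries against 33567 over the primed ones, a ratio of 14046 (interval 3888 to 115990). These lists kept their calls with an estimated correlation (adjusted p = 0.00108 for both), and fry gave the naive list an adjusted p of 6.34e-22. Of 18 core pluripotency genes TDGF1, ZFP42, NANOG, UTF1 and DPPA2 rose and 6 fell, among them FOXO1 by 2.76 ± 0.07 (median -0.14, adjusted p = 0.836). DPPA2 rose by 2.36 ± 0.07 and NANOG by 1.86 ± 0.12, but against Primed1 alone NANOG stood at 0.61 (adjusted p = 0.00119) and was not called. POU5F1, a core factor of pluripotency, stood at 0.59 ± 0.09 and was not called, whereas against Primed2 alone it was called at 1.53. KLF2 rose by 2.98 ± 0.10. Here and below, list members given for counts of 5 or fewer were named after their values were seen. Adjusted over the list alone, each list count in the 3 comparisons with primed cells was the same as over all genes.

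**Figure D1:**
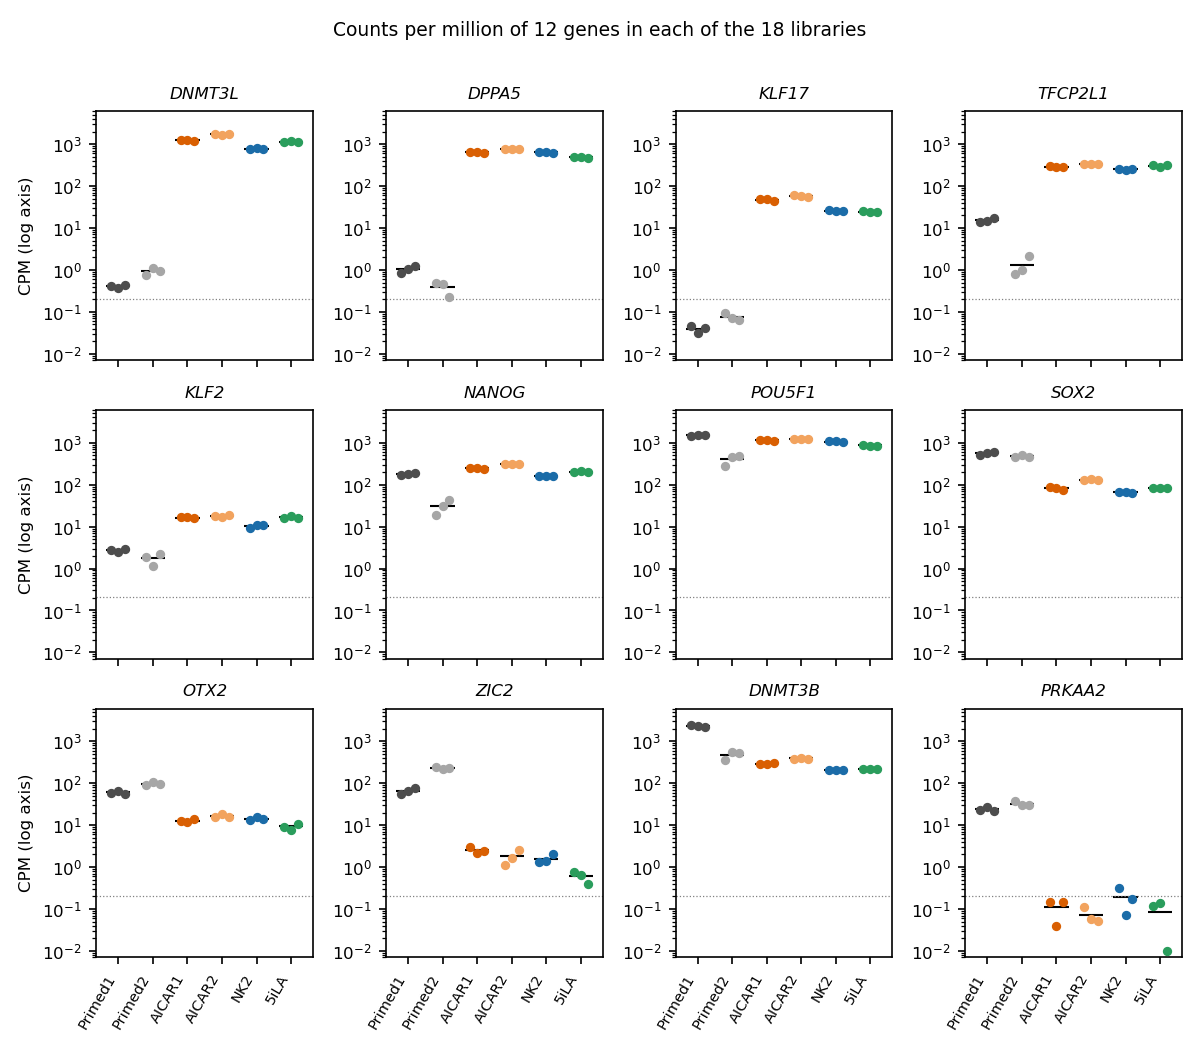
CPM on a log axis of 12 pluripotency and AMPK genes in each of the 18 libraries. Dots are libraries, lines are group means and the dotted line is the highest floor of 3 counts (0.208 CPM), with values under 0.01 drawn at 0.01.

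Among DNA methylation genes of AICAR against primed, DNMT3L, ZFP57 (by 5.68 ± 0.09), TET2 and TET1 rose, and UHRF2, DNMT3B and TET3 fell (median -0.21, mean 1.15, test upward with adjusted p = 0.793). DNMT3B fell by 1.63 ± 0.08 and lost its call against Primed2 alone (-0.48). Cleavage-stage genes, switched on in embryos around genome activation, rose in 17 of 20 cases (median 7.08, or 6.64 with genes at 0 counts at their bounds, adjusted p = 7.30e-07, and 0.00108 with an estimated correlation). TRIM43 went from 2 counts to 2473, a ratio of 1478 (interval 409 to 12207), and TRIM49 from 2 to 2315, a ratio of 1383 (interval 382 to 11428), in a family that shares sequence with paralogs. ZSCAN4 rose by 6.70 ± 0.29 to 3.46 CPM in AICAR1 and 7.63 in AICAR2. Of 19 germline genes kept silent by DNA methylation 13 rose, among them BRDT by 9.73 ± 0.09, and DAZL, TEX15, FKBP6 and TEX14 fell (median 3.53, adjusted p = 0.00545, and 0.0557 with an estimated correlation). Of 23 imprinted genes, expressed from one parental copy, MEG3+MIR770 rose by 10.43 ± 0.10, H19+MIR675 by 3.95 ± 0.12 and CDKN1C by 1.09 ± 0.06. PEG3+PEG3-AS1+ZIM2 went from 3 counts to 6267, a ratio of 2496 (interval 854 to 12107). Another 13 imprinted genes fell, such as SNRPN+SNURF by 2.14 ± 0.04, and the list's median was -1.06, its mean 0.17 and its test downward (adjusted p = 0.0348, 0.177 with an estimated correlation, 0.324 against Primed1 alone and 0.0569 with library totals).

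In AICAR against primed, subunits of complex I, the entry of the respiratory chain, rose in 14 of 38 cases (median 0.64, adjusted p = 4.23e-07, and 0.211 with an estimated correlation), led by NDUFAB1 at 2.82 ± 0.03 and NDUFV1 at 2.39 ± 0.03. Other oxidative phosphorylation subunits rose in 18 of 38 cases (median 0.97, adjusted p = 6.76e-11, and 0.158 with an estimated correlation), led by COX7B at 2.00 ± 0.04 and UQCRH at 1.82 ± 0.03. Of 25 glycolysis genes 10 fell and PFKL rose (median -0.73, adjusted p = 0.0106, 0.41 with an estimated correlation and 0.0999 against Primed2 alone). PDK1, a kinase that inhibits pyruvate dehydrogenase, fell by 2.82 ± 0.07 and the glucose carrier SLC2A3 by 2.58 ± 0.07. Among 24 AMPK genes 7 rose and PRKAA2, TXNIP and STRADA fell (median 0.71, adjusted p = 0.0817). PRKAA2, a catalytic subunit of AMPK, fell by 8.23 ± 0.18 from 24.4 and 32.5 CPM to 0.109 and 0.0731, whereas the other catalytic subunit, PRKAA1, stood at 0.31 ± 0.05 and was not called. DEPTOR, an inhibitor of mTOR, rose by 4.72 ± 0.05. Of 22 purine genes MTHFD2 and AMPD3 rose, and ADSSL1 (by 3.19 ± 0.16) and AMPD2 (by 2.10 ± 0.05) fell (median 0.27, adjusted p = 0.196). Among 26 sterol genes those that rose included RAI1+SREBF1 (by 2.70 ± 0.05), MVK and ACACA, and those that fell included NREP+STARD4+STARD4-AS1 and FADS1 (median 0.18, adjusted p = 0.119, and 0.0449 without replicate 1 of Primed1).

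Of the lists of signalling targets ERK targets passed downward and p53 targets upward in AICAR against primed, in a medium that per the protocol text held inhibitors of MEK and GSK3. Of 18 ERK feedback targets 16 fell (median -3.17, adjusted p = 2.04e-06, and 0.00974 with an estimated correlation), among them DUSP6 by 10.73 ± 0.17 and SPRY4 by 10.10 ± 0.10. Of 15 Wnt targets 6 fell, among them LEF1+LEF1-AS1 by 4.80 ± 0.21, and CDX1 rose (median -0.73, adjusted p = 0.198). WIF1 had 2 counts against 234, a ratio of 97.9 (interval 26.8 to 813). Of 12 STAT3 targets 6 rose, led by BCL3 at 3.01 ± 0.09, and BCL6 (by 2.89 ± 0.10), SOCS3 and LIFR fell (median 0.26, adjusted p = 0.861). Of 16 YAP targets 10 fell, AXL by 7.89 ± 0.10 and CTGF by 3.36 ± 0.08, and ANKRD1, DLC1 and F3 rose (median -1.62, adjusted p = 0.183). Of 20 p53 targets 10 rose, led by GDF15 at 3.13 ± 0.09, and FAS (by 3.25 ± 0.18), TP53I3, RHOBTB2+TNFRSF10B and BTG2 fell (median 1.03, adjusted p = 0.00762, and 0.209 with an estimated correlation). Of 18 stress genes of the endoplasmic reticulum 10 rose, TRIB3 by 5.52 ± 0.05 and CTH by 3.04 ± 0.04, and FLJ35024+VLDLR fell (median 1.19, adjusted p = 3.26e-05, and 0.115 with an estimated correlation). Of 30 S and G2/M phase genes CCNE1 rose by 2.13 ± 0.05 and the lowest stood at -0.88 (median 0.16, adjusted p = 0.125, with 0.0294 without replicate 1 of Primed1 and 0.0347 without replicate 2 of Primed2).

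Markers of other cell types moved in both directions in AICAR against primed. Trophoblast genes, of the placental lineage, rose in 11 of 17 cases, with CGA going from 8 counts to 563 (a ratio of 84.1) and GCM1 at 7.28 ± 0.18, and CCR7 and KRT7 fell (median 1.89, adjusted p = 0.0131, and 0.132 with an estimated correlation). Of 9 amnion genes ISL1+LOC642366 and ITGB6 rose and IGFBP5 (by 6.24 ± 0.15), TNC, HEY1, GABRP and IGFBP3 fell (median -1.70, adjusted p = 0.675). ITGB6 went from 2 counts to 75, a ratio of 44.8 (interval 12.0 to 377). Of 17 primitive endoderm genes HNF4A (by 7.11 ± 0.12), GATA6 and GATA4 rose and 9 fell, APOA1 by 5.29 ± 0.45 (median -1.28, adjusted p = 0.219). Of 14 mesendoderm genes 7 rose, and CER1 (34 counts, all in AICAR2, against 4371, a ratio of 108), LHX1 (by 5.57 ± 0.36), GSC, EOMES and TBX6 fell (median 0.53, mean -0.33, test upward with adjusted p = 0.389). Of 18 neuroectoderm genes 12 fell, DCX by 7.95 ± 0.28 and MAP2 by 7.87 ± 0.21, and ZIC1 and FABP7 rose (median -3.17, adjusted p = 0.0103, 0.128 with an estimated correlation and 0.413 against Primed1 alone). Neuroectoderm genes were higher in Primed2 than in Primed1, MAP2 at 130 and 4.00 CPM. Of 29 fibroblast genes 19 fell, THBS1 by 8.39 ± 0.14 and S100A4 by 7.80 ± 0.30 (median -2.36, adjusted p = 0.00781, and 0.188 with an estimated correlation). COL3A1+MIR3606, LUM, PRRX1, TWIST1 and TWIST2 rose, and of these COL3A1+MIR3606 stood at 0.183 CPM in Primed1, 19.6 in Primed2, 4.85 in AICAR1 and 78.8 in AICAR2.

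Over all genes of AICAR against primed, the largest rises under the naming rule were ZNF208 (8 counts to 48928, a ratio of 7308), ZNF729 (11 to 21546, a ratio of 2341), ZNF676 (6 to 11780, a ratio of 2346) and HORMAD1. ZNF257 went from 3 counts to 10278, a ratio of 4094 (interval 1400 to 19854). The ZNF genes encode zinc finger proteins and share sequence with paralogs. The largest falls were THY1, PTPRZ1, DUSP6, CXCL5 (0 counts, at least 3307-fold lower) and TRPC4 (0 counts, at least 972-fold lower). Tested genes had a median log2 difference of -0.12 with TMM scaling and -0.26 with library totals, and fold changes are relative to the former (-0.09 and -0.26 in NK2, -0.09 and -0.22 in 5iLA). With group as a random block (limma-voom) 4609 genes were called, and NANOG, THY1, LEF1+LEF1-AS1, WIF1, ITGB6, IGFBP5, APOA1, CER1, LHX1, DCX and MAP2 were not among them. That fit allows for 1 shared correlation of libraries within a group and is not a test with groups as the units. On log2(RPKM + 1) WIF1, LHX1 and ITGB6 lost their calls at -0.71, -0.92 and 0.33.

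**Figure D2:**
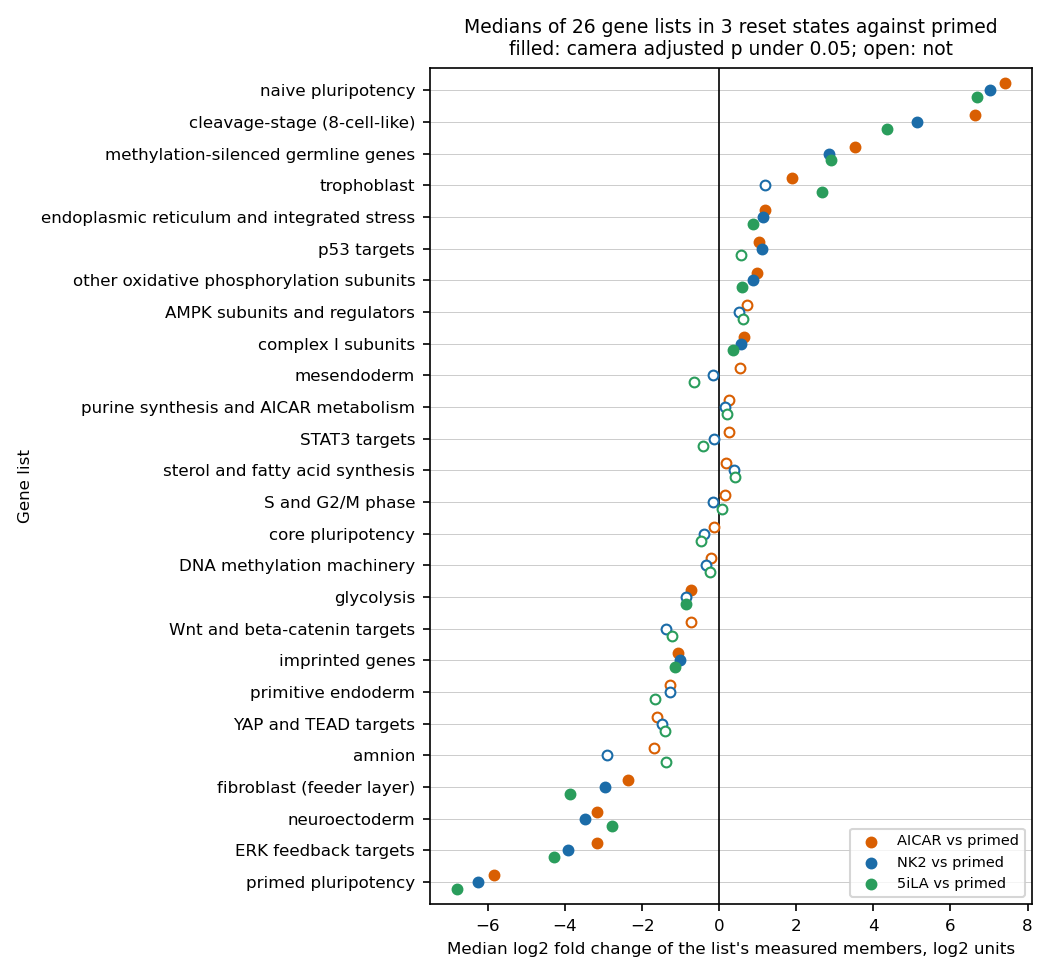
Median log2 fold change of each of the 26 gene lists in AICAR, NK2 and 5iLA against primed, with genes at 0 counts at their bounds. Filled points passed the list test with a preset correlation, and the naive list lies at 7.40 in AICAR, 7.02 in NK2 and 6.69 in 5iLA.

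The second comparison, NK2 against primed (3 libraries against 6), asks how cells labelled as having induced NANOG and KLF2 differed, in a medium that the labels do not tie to them. DNMT3L rose by 10.30 ± 0.05, DPPA5 by 9.97 ± 0.06, KLF17 by 8.78 ± 0.14, DPPA3 by 7.35 ± 0.06 and TFCP2L1 by 5.77 ± 0.07. ZIC2 fell by 6.27 ± 0.17, SOX2 by 2.98 ± 0.06, OTX2 by 2.44 ± 0.09 and DNMT3B by 2.33 ± 0.11. SPRY4, a feedback inhibitor of ERK signalling, had 0 counts against 39386 in primed cells and was at least 4637-fold lower. KLF2 rose by 2.24 ± 0.12. NANOG rose by 1.07 ± 0.14, but it lost its call against Primed1 alone (-0.18, adjusted p = 0.318), with library totals (0.90), on log2(RPKM + 1) (0.95) and without replicate 1 of Primed2 (0.95). PRKAA2 fell by 7.09 ± 0.22, and PRKAA1 (0.12 ± 0.06) and POU5F1 (0.44 ± 0.11) were not called, though POU5F1 was called against Primed2 alone at 1.37.

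In NK2 against primed 7121 genes were called, 2861 higher and 4260 lower. All 22 naive genes rose (median 7.02, adjusted p = 9.78e-12, and 0.00192 with an estimated correlation), with HORMAD1 going from 4 counts to 3576 (a ratio of 2531) and KHDC1L at 11.46 ± 0.07. All 23 primed genes fell (median -6.88, or -6.27 with bounds, adjusted p = 1.91e-10, and 0.0015 with an estimated correlation). PTPRZ1 had 1 count against 39336, a ratio of 13893 (interval 2493 to 548740), and THY1 had 1 count against 33567, a ratio of 11855 (interval 2128 to 468270). Core genes NANOG, ZFP42, UTF1 and DPPA2 rose and 7 fell, FOXO1 by 3.08 ± 0.10 (adjusted p = 0.393). ERK targets fell in 16 of 18 cases and SPHK1 rose (adjusted p = 1.67e-05, and 0.0189 with an estimated correlation), with DUSP6 at 2 counts against 9651, a ratio of 1704 (interval 472 to 14075). Cleavage-stage genes rose in 17 of 20 cases (median 5.93, or 5.14 with bounds, adjusted p = 1.12e-05, and 0.00242 with an estimated correlation). TRIM43 went from 2 counts to 408, a ratio of 578 (interval 159 to 4786), and KDM4E from 1 to 319, a ratio of 903 (interval 161 to 35786). Germline genes rose in 12 of 19 cases, BRDT by 10.10 ± 0.10, and DAZL, TEX15 and TEX14 fell (adjusted p = 0.00438, and 0.0558 with an estimated correlation). Imprinted MEG3+MIR770 (by 11.03 ± 0.10), PEG3+PEG3-AS1+ZIM2 (from 3 counts to 2020, a ratio of 1906, interval 651 to 9252), H19+MIR675 and CDKN1C rose and 13 others fell (adjusted p = 0.0382, 0.19 with an estimated correlation, 0.262 against Primed1 alone and 0.0654 with library totals).

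Respiratory chain genes rose in NK2 as well, complex I in 11 of 38 cases (median 0.58, adjusted p = 1.23e-05, and 0.324 with an estimated correlation) with NDUFAB1 at 2.52 ± 0.04 and NDUFV1 at 2.36 ± 0.04. The other subunits rose in 15 of 38 cases (median 0.89, adjusted p = 2.38e-09, and 0.196 with an estimated correlation) with COX7B at 1.85 ± 0.05 and UQCRH at 1.64 ± 0.04. Stress genes rose in 10 of 18 cases (adjusted p = 1.12e-05, and 0.0806 with an estimated correlation), TRIB3 by 6.40 ± 0.06 and CTH by 3.11 ± 0.05. P53 targets rose in 10 of 20 cases, GDF15 by 3.68 ± 0.10, and FAS (by 2.71 ± 0.23), TP53I3, RHOBTB2+TNFRSF10B and BTG2 fell (adjusted p = 0.0131, and 0.289 with an estimated correlation). Neuroectoderm genes fell in 15 of 18 cases, DCX to 2 counts from 3473 (ratio 613, interval 170 to 5066) and MAP2 to 0 counts (at least 1239-fold), and ZIC1 and FABP7 rose (adjusted p = 0.00438, 0.0806 with an estimated correlation and 0.255 against Primed1 alone). Fibroblast genes fell in 19 of 29 cases, THBS1 by 10.28 ± 0.24 and S100A4 to 0 counts (at least 157-fold), and TWIST1 and TWIST2 rose (adjusted p = 0.000321, and 0.0883 with an estimated correlation).

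The other 14 lists of NK2 against primed did not pass. DNA methylation genes gave a median of -0.35 and a mean of 0.91 with the test downward (adjusted p = 0.969): DNMT3L, ZFP57 (by 5.67 ± 0.10), TET2 and TET1 rose and DNMT3B, DNMT1, UHRF2 and UHRF1 fell. Of AMPK genes 10 rose, DEPTOR by 4.41 ± 0.05, and PRKAA2, STRADA and TXNIP fell (adjusted p = 0.145). Of purine genes MTHFD2 (by 1.85 ± 0.04), HPRT1, SLC29A1 and AMPD3 rose and ADSSL1 (by 2.26 ± 0.18) and AMPD2 fell (adjusted p = 0.264). Glycolysis genes fell in 10 cases, PDK1 by 3.06 ± 0.09 and SLC2A3 by 1.88 ± 0.09, and PFKL and ENO2 rose (adjusted p = 0.0805). Sterol genes rose in 8 cases, RAI1+SREBF1 by 2.50 ± 0.05, and those that fell included NREP+STARD4+STARD4-AS1 and FADS1 (adjusted p = 0.0805, and 0.0468 without replicate 1 of Primed1). Wnt targets fell in 9 cases, LEF1+LEF1-AS1 by 5.06 ± 0.29 and WIF1 to 0 counts (at least 27.5-fold, with no call on log2(RPKM + 1)), and CDX1 and NOTUM rose (adjusted p = 0.145). Of STAT3 targets CISH (by 2.85 ± 0.19), BCL3, IL6ST and IRF1 rose and BCL6 (by 2.70 ± 0.14), SOCS3, PIM1, STAT3 and LIFR fell (median -0.14, mean 0.17, test downward with adjusted p = 0.895). YAP targets fell in 9 cases, AXL by 7.67 ± 0.14 and CTGF by 4.17 ± 0.12, and ANKRD1, DLC1 and F3 rose (adjusted p = 0.192). Trophoblast genes rose in 9 cases, GCM1 by 5.56 ± 0.27, and CCR7 (by 5.52 ± 0.45), ENPEP and KRT7 fell (adjusted p = 0.162). Of amnion genes ISL1+LOC642366 and ITGB6 rose and TNC (by 6.35 ± 0.20), IGFBP5 (by 6.23 ± 0.19), GABRP, HEY1 and IGFBP3 fell (adjusted p = 0.262).

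Primitive endoderm genes HNF4A (by 7.56 ± 0.13), GATA6 and GATA4 rose in NK2 and 8 fell, APOA1 to 0 counts (at least 134-fold, adjusted p = 0.264 for the list). Of mesendoderm genes 6 rose and 6 fell, CER1 by 7.90 ± 0.49 and GSC to 1 count from 96 (ratio 33.9, interval 5.94 to 1353, with no call on log2(RPKM + 1)), with a median of -0.16 and the test upward (adjusted p = 0.851). Of S and G2/M genes CCNE1 (by 1.99 ± 0.06) and UBE2C rose and CENPF (by 1.17 ± 0.04, with -0.91 and no call against Primed1 alone) and BUB1B+PAK6 fell (adjusted p = 0.393). Over all genes the largest rises were ZNF208 (8 counts to 18146, a ratio of 6422), ZNF676 (6 to 6611, a ratio of 3120), HORMAD1, ZNF728 (2 counts to 2583, a ratio of 3657, interval 1011 to 30211) and ZNF736 (from 0 counts, at least 1472-fold higher). The largest falls included SPRY4, PTPRZ1, THY1 and CXCL5 (0 counts, at least 1396-fold lower).

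The third comparison, 5iLA against primed (3 libraries against 6), asks the same of the inhibitor culture. DNMT3L rose by 10.85 ± 0.05, DPPA5 by 9.59 ± 0.06, KLF17 by 8.68 ± 0.15, DPPA3 by 7.89 ± 0.06 and TFCP2L1 by 6.06 ± 0.07. ZIC2 fell by 7.69 ± 0.20, OTX2 by 3.03 ± 0.10, SOX2 by 2.63 ± 0.06 and DNMT3B by 2.25 ± 0.11, and PTPRZ1 had 0 counts and was at least 4405-fold lower. KLF2 rose by 2.94 ± 0.12, and NANOG rose by 1.41 ± 0.14 but stood at 0.16 (adjusted p = 0.36) against Primed1 alone. PRKAA2 fell by 8.32 ± 0.26, and PRKAA1 (-0.01 ± 0.06) and POU5F1 (0.13 ± 0.12) were not called, though POU5F1 was called against Primed2 alone at 1.06.

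In 5iLA against primed 7037 genes were called, 2814 higher and 4223 lower. Of 22 naive genes 21 rose (median 6.69, adjusted p = 6.63e-12, and 0.0018 with an estimated correlation) and TFAP2C stood at 0.72 ± 0.08, with HORMAD1 going from 4 counts to 3782 (a ratio of 2814) and KHDC1L at 11.02 ± 0.07. All 23 primed genes fell (median -7.44, or -6.80 with bounds, adjusted p = 9.33e-11, and 0.0013 with an estimated correlation), THY1 to 2 counts from 33567 (ratio 5638, interval 1561 to 46561). Core genes NANOG, ZFP42, UTF1 and DPPA2 rose and 8 fell, FOXO1 by 3.02 ± 0.10 (adjusted p = 0.376). ERK targets fell in 16 of 18 cases (adjusted p = 1.49e-06, and 0.00747 with an estimated correlation), SPRY4 by 10.54 ± 0.14 and DUSP6 to 1 count from 9651 (ratio 3242, interval 582 to 128080). Cleavage-stage genes rose in 16 of 20 cases and RFPL1+RFPL1-AS1 fell (median 5.46, or 4.36 with bounds, adjusted p = 0.00013, and 0.00641 with an estimated correlation), with KDM4E going from 1 count to 279, a ratio of 830 (interval 148 to 32918). Germline genes rose in 12 of 19 cases, BRDT by 9.94 ± 0.10, and DAZL, TEX15 and TEX14 fell (adjusted p = 0.00502, and 0.0534 with an estimated correlation). Imprinted MEG3+MIR770 (by 11.31 ± 0.10), PEG3+PEG3-AS1+ZIM2 (from 3 counts to 735, a ratio of 729, interval 249 to 3544), H19+MIR675 and CDKN1C rose and 12 others fell (mean 0.05 with a median of -1.14, adjusted p = 0.0349, 0.17 with an estimated correlation, 0.273 against Primed1 alone and 0.06 with library totals).

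Complex I genes rose in 9 of 38 cases in 5iLA (median 0.36, adjusted p = 0.00669, and 0.503 with an estimated correlation), NDUFAB1 by 2.39 ± 0.04 and NDUFV1 by 1.78 ± 0.04. Of the other subunits UQCRH (by 1.60 ± 0.04), COX7B (by 1.54 ± 0.05), COX5B and SDHD rose (median 0.60, adjusted p = 1.49e-06, and 0.296 with an estimated correlation). Glycolysis genes fell in 10 of 25 cases (adjusted p = 0.00526, and 0.331 with an estimated correlation), PDK1 by 3.46 ± 0.10 and SLC2A3 by 2.29 ± 0.10. Trophoblast genes rose in 13 of 17 cases and CCR7 and KRT7 fell (median 2.67, adjusted p = 0.0089, and 0.105 with an estimated correlation), with CGA going from 8 counts to 906 (a ratio of 337) and HSD3B1 going from 1 count to 53, a ratio of 158 (interval 27.1 to 6347). Neuroectoderm genes fell in 13 of 18 cases and ZIC1 and FABP7 rose (adjusted p = 0.00699, 0.105 with an estimated correlation and 0.319 against Primed1 alone), DCX by 7.45 ± 0.38 and MAP2 to 3 counts from 10527 (ratio 1179, interval 403 to 5717). Fibroblast genes fell in 21 of 29 cases and TWIST1 and TWIST2 rose (adjusted p = 0.000265, and 0.105 with an estimated correlation), S100A4 to 0 counts (at least 150-fold) and THBS1 to 1 count from 44471 (ratio 14940, interval 2681 to 590120). Stress genes rose in 8 of 18 cases, TRIB3 by 6.0 ± 0.06 and CTH by 2.77 ± 0.05 (adjusted p = 0.000265, and 0.122 with an estimated correlation).

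The other lists of 5iLA against primed did not pass. DNA methylation genes had a median of -0.25 and a mean of 1.14 with the test upward (adjusted p = 0.759): DNMT3L, ZFP57 (by 5.49 ± 0.11), TET2 and TET1 rose and DNMT3B and DNMT1 fell. Of AMPK genes 9 rose, DEPTOR by 4.24 ± 0.06, and PRKAA2, TXNIP and STRADA fell (adjusted p = 0.0693, and 0.0462 without replicate 3 of Primed1). Of purine genes MTHFD2, HPRT1 and AMPD3 rose and ADSSL1 (by 3.56 ± 0.23), AMPD2 (by 1.96 ± 0.07), ADK and IMPDH1 fell (median 0.19, mean -0.09, test upward with adjusted p = 0.69). Sterol genes that rose included RAI1+SREBF1 (by 2.58 ± 0.05), MVK and INSIG1, and those that fell included NREP+STARD4+STARD4-AS1, FADS1, FADS2 and ACACB (adjusted p = 0.0778, and 0.0405 without replicate 1 of Primed1). Wnt targets fell in 8 cases, LEF1+LEF1-AS1 by 4.95 ± 0.29 and WIF1 to 1 count from 234 (ratio 78.6, interval 14.0 to 3118), and CDX1 rose (adjusted p = 0.0881). Of STAT3 targets BCL3 (by 3.12 ± 0.11), IL6ST, CISH, IRF1 and CEBPD rose and BCL6 (by 2.95 ± 0.14), PIM1, SOCS3 and LIFR fell (median -0.42, mean 0.09, test downward with adjusted p = 0.715). YAP targets fell in 10 cases, AXL by 7.30 ± 0.13 and CTGF by 5.53 ± 0.14, and ANKRD1 and DLC1 rose (adjusted p = 0.0609, with 0.0405 and 0.0430 without replicates 1 and 3 of Primed1 and 0.0459 without replicate 2 of 5iLA). P53 targets rose in 7 cases and FAS (by 4.04 ± 0.28), TP53I3 (by 2.60 ± 0.14), RHOBTB2+TNFRSF10B and RRM2B fell (adjusted p = 0.0547, with 0.0460 and 0.0430 without replicates 1 and 3 of Primed1). Of amnion genes ISL1+LOC642366 and ITGB6 (2 counts to 78, a ratio of 116, interval 31.1 to 975) rose and IGFBP5 (by 8.21 ± 0.24), TNC, GABRP, HEY1 and IGFBP3 fell (adjusted p = 0.52).

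Primitive endoderm genes HNF4A (by 7.35 ± 0.13), GATA6 and GATA4 rose in 5iLA and 11 fell, APOA1 to 0 counts (at least 128-fold, adjusted p = 0.218 for the list). Mesendoderm genes that rose included MIXL1, HAND1, NODAL and WNT3, and 7 fell, with LHX1 at 2 counts from 436 (ratio 73.2, interval 20.2 to 607) and CER1 at 2 from 4371 (ratio 734, interval 203 to 6065). The mesendoderm median was -0.67 with the test upward (adjusted p = 0.98). Of S and G2/M genes CCNE1 rose by 1.83 ± 0.06 and BUB1B+PAK6 fell by 1.00 ± 0.04 (adjusted p = 0.52 for the list), and BUB1B+PAK6 was under the fold threshold without replicate 1, 2 or 3 of Primed1, replicate 1, 2 or 3 of 5iLA or replicate 2 of Primed2. Over all genes the largest rises were ZNF208 (8 counts to 23572, a ratio of 8770), ZNF676 (6 to 7079, a ratio of 3512), ZNF729 (11 to 7054, a ratio of 1909), HORMAD1 and ZNF736 (from 0 counts, at least 1409-fold higher). The largest falls were PTPRZ1, THBS1 and, each at 0 counts, CXCL5 (at least 1328-fold lower), STC1 (at least 1027-fold) and GREM1 (at least 872-fold). WIF1, LHX1, ITGB6 and HSD3B1 lost their calls on log2(RPKM + 1), at -0.71, -0.93, 0.77 and 0.76.

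The AICAR, NK2 and 5iLA changes were then compared gene by gene, since the series asks about naive pluripotency. AICAR and NK2 shared 2306 genes called higher and 3736 called lower against primed, where independent calls would give 494 and 1190, and 15 genes were called in opposite directions. AICAR and 5iLA shared 2277 higher and 3755 lower genes, where independent calls would give 486 and 1180, and 10 had opposite directions. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.948 with NK2 and 0.947 with 5iLA (covariance 5.22 and 5.24), against medians of 0.394 and 0.388 (covariance 0.00896 and 0.00897) in 20 simulations of unchanged groups, which share the error of the primed libraries. The simulations hold error between libraries of a group only, and no error between groups such as that between Primed1 and Primed2. With AICAR and the other group set against different primed groups the covariance was 4.80 and 4.84 for NK2 and 4.81 and 4.87 for 5iLA, and 216 and 197 genes for NK2 and 208 and 197 for 5iLA were called in opposite directions. Among genes called in NK2 against primed, whether or not called in AICAR, the AICAR change was a median 0.949 of the NK2 change (10th to 90th percentile 0.539 to 1.38). Among genes called in 5iLA against primed it was a median 0.951 of the 5iLA change (0.537 to 1.39). List shares were taken over members called in NK2 or in 5iLA, whether or not called in AICAR. Genes were thus chosen by the change that each share divides by, which can lower a share, and the reverse share was not taken. The shares over all called genes therefore do not show that AICAR cells fell short of the other states. Naive genes had a median share of 1.06 of the NK2 and 1.07 of the 5iLA change, primed genes 0.913 and 0.862, cleavage-stage genes 1.16 and 1.37, complex I genes 1.12 and 1.34, and fibroblast genes 0.826 and 0.719.

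**Figure D3:**
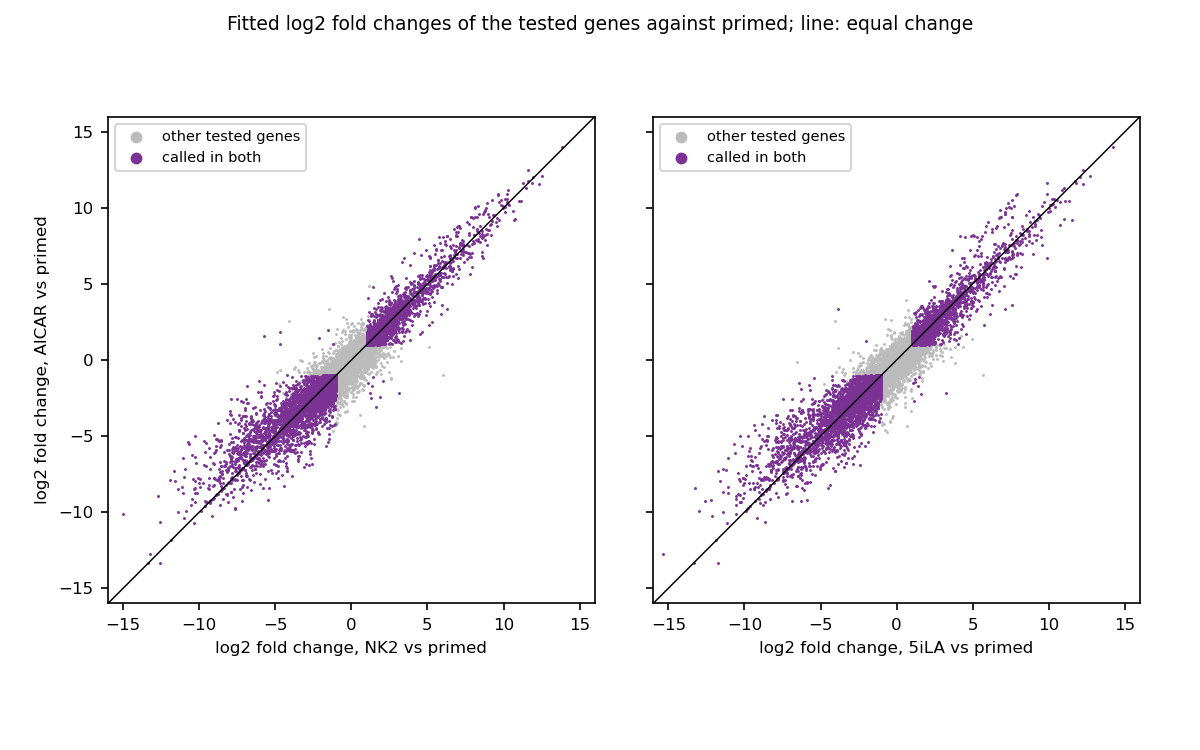
Fitted log2 fold changes against primed of the 15645 tested genes, AICAR on the vertical axes and NK2 (left) or 5iLA (right) on the horizontal axes. Purple points were called in both, the line marks equal change, and values of genes with few counts are fitted, not bounds.

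The fourth comparison, AICAR against NK2 (6 libraries against 3), asks where the AICAR cells differ from cells labelled as having induced factors. COL3A1+MIR3606, a fibrillar collagen, was higher by 4.84 ± 0.36, METTL7A by 4.08 ± 0.25, XKR4 by 3.58 ± 0.34, ZNF90 by 3.56 ± 0.08 and CYP2E1 by 3.41 ± 0.30. RPE65, an enzyme of the visual cycle, had 5 counts against 152 (a ratio of 72.0), and OC90 fell by 5.25 ± 0.27, HHLA1 by 5.17 ± 0.33, TRPM5 by 4.71 ± 0.43 and SLCO1C1 by 4.25 ± 0.38. On log2(RPKM + 1) TRPM5 (-0.70), SLCO1C1 (-0.71) and XKR4 (0.68) lost their calls. The naive genes KLF4 (by 1.71 ± 0.07), TBX3 (by 1.90 ± 0.08), ARGFX and CBFA2T2 were higher in AICAR cells, and LEFTY2, a target and inhibitor of NODAL signalling, was higher by 2.63 ± 0.16. These changes average AICAR groups that differed: COL3A1+MIR3606 (4.85 CPM in AICAR1 and 78.8 in AICAR2), HHLA1 (0.251 and 4.78, with 39.2 in NK2), OC90, RPE65, METTL7A, XKR4 and LEFTY2 were higher in AICAR2 than in AICAR1, and CYP2E1 and TRPM5 lower.

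In AICAR against NK2 1422 genes were called, 649 higher and 773 lower. The 10 lists that passed, all upward, lost their calls with an estimated correlation. They were naive pluripotency (median 0.40, adjusted p = 0.000302, and 0.0695 with an estimated correlation), primed pluripotency (0.43, adjusted p = 0.00114, and 0.0695), core pluripotency (0.35, adjusted p = 0.0134, and 0.613), DNA methylation (0.12, adjusted p = 0.0467, and 0.353), complex I (0.13, adjusted p = 0.0134, and 0.613) and the other oxidative phosphorylation subunits (0.15, adjusted p = 0.00114, and 0.585). The others were trophoblast (1.09, adjusted p = 0.0118, and 0.185), fibroblast (0.77, or 0.55 with bounds, adjusted p = 0.0028, and 0.224), cleavage-stage (1.00, adjusted p = 0.00385, and 0.0695) and S and G2/M phase genes (0.34, adjusted p = 2.92e-07, and 0.353). Members called in these lists were higher: 4 naive genes, 9 trophoblast genes, 10 fibroblast genes (11 adjusted over the list alone), 10 cleavage-stage genes, primed genes that included SOX11, GPC4, SALL2 and CDH2, SALL4 among core genes and UHRF1 among DNA methylation genes. No complex I, other oxidative phosphorylation or S and G2/M member was called, with the highest at 0.42, 0.61 and 0.67. With AICAR1 alone 875 genes were called and 2 lists passed, naive pluripotency and the other oxidative phosphorylation subunits, and with AICAR2 alone 2360 genes were called. DNA methylation genes had adjusted p = 0.055 without replicate 2 of NK2.

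The 16 other lists did not pass in AICAR against NK2, with p from 0.0528 for mesendoderm to 0.912. LEFTY2, LEFTY1, HAND1 and T were higher and TBX6 and LHX1 lower among mesendoderm genes, and mesendoderm passed without replicate 3 of NK2 (adjusted p = 0.0377), without replicate 1, 2 or 3 of AICAR1 and without replicate 1 or 2 of AICAR2 (0.0456 to 0.0497). Among ERK targets SPRY2, FOS and SPRY4 (21 counts against 0) were higher and CCND1, DUSP5 and FOSL1 lower, with a mean of 0.14 and a median of -0.34. RPTOR of the AMPK list was higher by 1.32 ± 0.05 and CHAC1 of the stress list by 1.41 ± 0.15. HK1 was higher and ALDOC and SLC16A3 lower among glycolysis genes, TCF7 higher and LGR5 lower among Wnt targets, ANKRD1 lower among YAP targets and NDN higher among imprinted genes. TNC, VTCN1 and IGFBP3 were higher among amnion genes, FOXA2 and BMP2 higher (3 higher adjusted over the list alone) and NID2 lower among primitive endoderm genes, with a median of 0.20 and the test downward. NR2F1 and NR2F2 were higher among neuroectoderm genes (1 adjusted over the list alone), and TEX15, TDRD1 and SPATA22 higher and DPEP3 lower among germline genes (mean 0.12, median -0.02). Purine genes had a median of 0.02 and a mean of -0.08, and no purine, STAT3 or p53 gene reached a log2 fold change of 1, the largest sizes being -0.93, 0.64 and 0.73.

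The fifth comparison, AICAR against 5iLA (6 libraries against 3), asks the same against the inhibitor culture. COL3A1+MIR3606 was higher by 7.25 ± 0.49, COL1A2 by 4.71 ± 0.47, NEFL, a neurofilament gene, by 4.25 ± 0.20, TRIM64B by 3.65 ± 0.37 and SFTPD by 3.29 ± 0.27. RPE65 had 5 counts against 118 (a ratio of 58.8), and OC90 fell by 5.38 ± 0.26, HHLA1 by 5.00 ± 0.34, PDE3A by 4.49 ± 0.37 and ATP6V0D2 by 4.00 ± 0.21, and RPE65 (-0.97) and PDE3A (-0.31) lost their calls on log2(RPKM + 1). Cleavage-stage genes were higher in 14 of 20 cases (median 2.07, adjusted p = 4.40e-05, and 0.0114 with an estimated correlation), ZSCAN4 by 2.40 ± 0.25 and TRIM43 by 2.94 ± 0.13. The naive genes TBX3 (by 2.35 ± 0.08), KLF17 (by 1.10 ± 0.06), TFAP2C and CBFA2T2 were higher. Here too the AICAR groups differed, with COL3A1+MIR3606, COL1A2, TRIM64B, OC90, HHLA1, RPE65 and ZSCAN4 higher in AICAR2 than in AICAR1 and ATP6V0D2 lower.

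In AICAR against 5iLA 1437 genes were called, 579 higher and 858 lower. Primed genes were higher in 8 of 23 cases (median 0.73, or 0.63 with bounds, adjusted p = 6.25e-05, and 0.0264 with an estimated correlation). Another 8 lists passed upward and lost their calls with an estimated correlation: naive pluripotency (0.46, adjusted p = 8.47e-05, and 0.0658), core pluripotency (0.28, adjusted p = 0.00236, and 0.493), complex I (0.36, adjusted p = 1.24e-13, and 0.0916) and the other oxidative phosphorylation subunits (0.41, adjusted p = 6.91e-18, and 0.0734). They also included mesendoderm (0.64, adjusted p = 0.00342, and 0.0707), fibroblast (0.99, or 0.92 with bounds, adjusted p = 0.000417, and 0.0916), p53 targets (0.49, adjusted p = 1.27e-05, and 0.0707) and S and G2/M genes (0.16, adjusted p = 0.00321, and 0.597). Complex I members lay between 0.18 and 0.77 and the other subunits between 0.01 and 0.71. PRDM14 was the core gene called higher, LEFTY1 and LEFTY2 the mesendoderm genes, and 12 fibroblast genes were higher with COL6A1 lower. The highest p53 and S and G2/M members stood at 0.89 and 0.61. With AICAR1 alone the core, fibroblast and S and G2/M lists lost their calls (adjusted p = 0.245, 0.0898 and 0.548).

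The 16 lists that did not pass in AICAR against 5iLA had p from 0.0529 for purine, YAP and stress genes to 0.953. CCR7, CGA, CGB and KRT18+KRT8 were lower among trophoblast genes (median -0.16, adjusted p = 0.268). SOCS1 and PIM1 were higher among STAT3 targets (median -0.03, mean 0.23), SP5 and APCDD1 among Wnt targets, and CTGF, AMOTL2 and ARHGEF17 among YAP targets with WWC1 and NT5E lower. SPRY2, FOS, SPRY1 and MYC were higher and ETV5, DUSP5 and FOSL1 lower among ERK targets, and SLC16A3 was the glycolysis gene lower. BMP2 was higher and GATA6 and PDGFRA lower among primitive endoderm genes (3 higher adjusted over the list alone, median -0.12, mean 0.33), and neuroectoderm genes included FABP7, POU3F2 and SOX1 higher and PAX6 and NES lower (2 and 2 adjusted over the list alone). TNC and IGFBP5 were higher and ITGB6 lower among amnion genes, DDX4, SPATA22 and MAEL higher and FKBP6 and CCDC169+CCDC169-SOHLH2+SOHLH2 lower among germline genes (mean 0.10, median -0.01), and DLK1 and PEG3+PEG3-AS1+ZIM2 higher and HYMAI+PLAGL1 lower among imprinted genes. DNA methylation, AMPK, purine and stress genes stayed under a log2 fold change of 1, the largest sizes being -0.85, 0.99, -0.53 and 0.82, and sterol genes had a mean of -0.02 and a median of 0.01. Leaving out single libraries let YAP targets (p 0.0388 to 0.0499 without replicate 1, 2 or 3 of 5iLA, 1 or 2 of AICAR1, or 2 or 3 of AICAR2), stress genes (0.0467 without replicate 1 of AICAR1 and 0.0459 without replicate 3 of AICAR2) and purine genes (0.0467 without replicate 1 of AICAR1) pass.

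The sixth comparison, AICAR2 against AICAR1 (3 libraries against 3), measures how far groups with the same treatment label differ. COL3A1+MIR3606 was higher in AICAR2 by 4.01 ± 0.22 (78.8 ± 10.1 against 4.85 ± 0.889 CPM), HHLA1 by 4.28 ± 0.75, LUM by 3.58 ± 0.45 and the cadherin CDH2 by 3.56 ± 0.28. NRK had 92 counts against 3, a ratio of 37.3 (interval 12.4 to 184). TENM1 fell by 3.88 ± 0.24, ADAMTS14 by 3.71 ± 0.30, CHP2 by 3.43 ± 0.51 and MYO18B by 3.15 ± 0.31. On log2(RPKM + 1) NRK, LUM, CDH2, TENM1, ADAMTS14, CHP2 and MYO18B lost their calls (0.27, 0.88, 0.73, -0.81, -0.69, -0.57 and -0.47).

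In AICAR2 against AICAR1 1323 genes were called, 476 higher and 847 lower. Fibroblast genes were higher in 11 of 29 cases (12 adjusted over the list alone, median 0.90, adjusted p = 0.000113, and 0.121 with an estimated correlation). Primed genes were higher in 6 cases and SFRP1 lower (median 0.41, adjusted p = 0.00611, and 0.121 with an estimated correlation). ZSCAN4, TRIM49, TPRX1, RFPL2 and LEUTX were higher among cleavage-stage genes (median 0.89, adjusted p = 0.00611, and 0.113 with an estimated correlation). S and G2/M genes had a median of 0.34 (adjusted p = 1.47e-10, and 0.388 with an estimated correlation), with CENPE higher, and core genes a median of 0.39 with the highest at 0.74 (adjusted p = 0.00503, and 0.519 with an estimated correlation). The other 21 lists did not pass, with p from 0.0523 for the other oxidative phosphorylation subunits to 0.705. Those subunits passed without replicate 1 or 2 of AICAR1 (adjusted p = 0.0478 and 0.0309) and without replicate 2 of AICAR2 (0.0389), and Wnt targets without replicate 1 of AICAR1 (0.0478) and without replicate 2 of AICAR2 (0.0415). Among Wnt targets LGR5, SP5, TNFRSF19 and APCDD1 were higher, among trophoblast genes EPAS1, CYP19A1, HSD3B1 and VGLL1, among amnion genes TNC, IGFBP5, GABRP and VTCN1, among primitive endoderm genes RSPO3 and APOA1, and among neuroectoderm genes NR2F1, NR2F2, OTX1 and LOC100288346+NCAM1. LEFTY2, MIXL1, T and CER1 were higher and TBX6 and EOMES lower among mesendoderm genes, and PPARGC1A was higher and ALDOC, SLC16A3, ADSSL1, IRF1 and TRIB3 were lower in the lists of energy metabolism, STAT3 and stress. TDRD1 was higher (not adjusted over the list alone) and MOV10L1 lower among germline genes, DIRAS3 higher and L3MBTL1 lower among imprinted genes, and LOC728463+TGFB2 higher and ANKRD1 and ARHGEF17 lower among YAP targets (median -0.26). ERK targets had a median of 0.10 with the test downward (adjusted p = 0.678). No naive, DNA methylation, respiratory chain, sterol or p53 gene reached a log2 fold change of 1, the largest sizes being -0.93, 0.69, 0.50, -0.98 and -0.87.

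**Figure D4:**
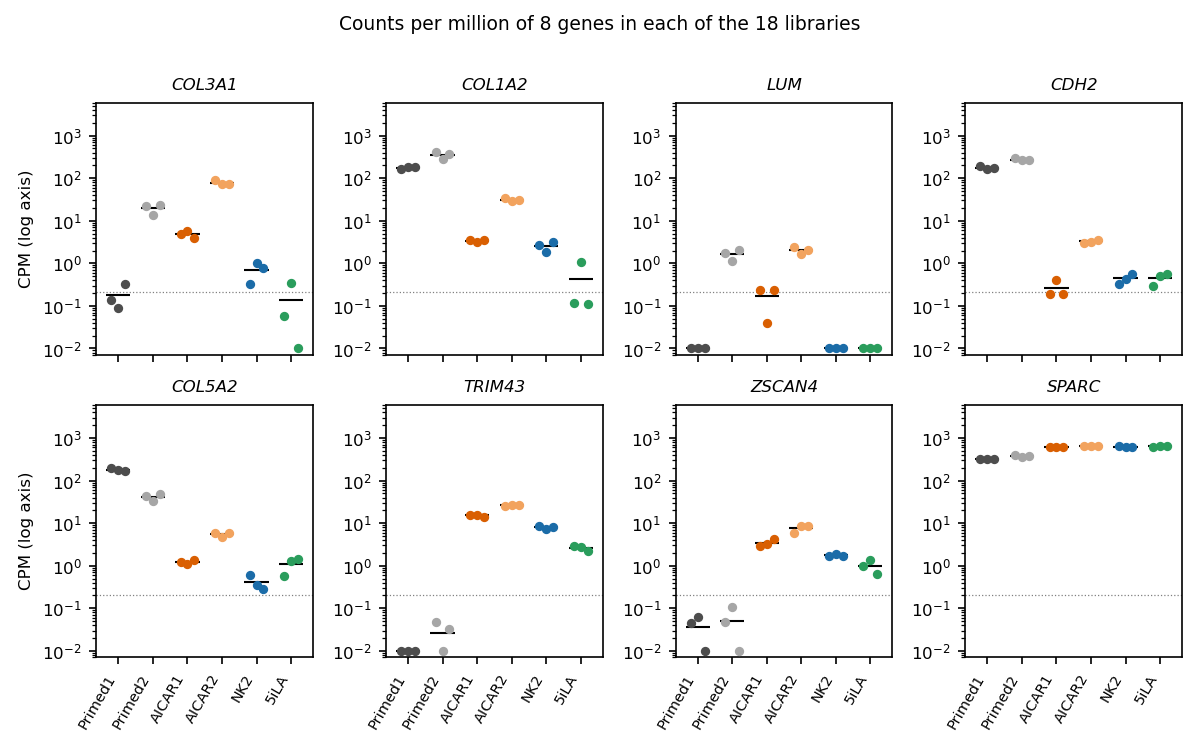
CPM on a log axis of 8 genes in each of the 18 libraries, with dots for libraries and lines for group means. COL3A1 stands at 78.8 CPM in AICAR2 and 4.85 in AICAR1, whereas SPARC stands at 658 and 616.

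The seventh comparison, Primed2 against Primed1 (3 libraries against 3), measures how far the references differ. LGI1 was at least 653-fold higher in Primed2, LMX1A, a transcription factor of the roof plate and midbrain, at least 340-fold and LOC145845 at least 207-fold, each from 0 counts. HOXB1, a patterning gene, went from 1 count to 1175, a ratio of 1271 (interval 228 to 50253), and GREB1L was higher by 9.50 ± 0.21. TRIM4 had 0 counts in Primed2 and was at least 138-fold lower, ZNF253 fell by 7.09 ± 0.17, CH25H by 6.93 ± 0.22, PSMD5 by 6.85 ± 0.11 and PUS7L by 6.84 ± 0.23. POU5F1 stood at 410 ± 109 CPM in Primed2 and 1495 ± 26.5 in Primed1, and the neural gene SOX1 at 32.8 ± 6.20 and 0.506 ± 0.122.

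In Primed2 against Primed1 3815 genes were called, 1841 higher and 1974 lower. Core pluripotency genes fell in 13 of 18 cases (median -1.54, adjusted p = 7.18e-08, and 0.223 with an estimated correlation). Neuroectoderm genes rose in 14 of 18 cases and SOX3 fell (median 3.63, adjusted p = 0.000102, and 0.0499 with an estimated correlation), and primitive endoderm genes rose in 10 of 17 cases and BMP2 fell (median 2.99, adjusted p = 1.63e-05, and 0.0105 with an estimated correlation). Wnt targets rose in 8 of 15 cases and WIF1 fell (median 1.85, adjusted p = 0.00748, and 0.189 with an estimated correlation). Imprinted genes rose in 7 of 23 cases (8 adjusted over the list alone) and MAGEL2 fell (median 0.57, or 0.56 with bounds, adjusted p = 0.0135, and 0.189 with an estimated correlation). Stress genes fell in 8 of 18 cases (median -0.87, adjusted p = 9.63e-07, and 0.0856 with an estimated correlation). MTHFD2, ADSL and NDUFA4L2+SHMT2 fell among purine genes (adjusted p = 0.00161, and 0.223 with an estimated correlation), SLC16A3, HK1 and HK2 among glycolysis genes (adjusted p = 0.00106, and 0.446) and 3 genes among sterol genes (adjusted p = 9.63e-05, and 0.371). Complex I genes had a median of -0.19 (adjusted p = 0.0107, 0.644 with an estimated correlation, 0.169 with library totals and 0.0599 without replicate 1 of Primed2) and the other subunits a median of -0.25 (adjusted p = 0.000143, and 0.585 with an estimated correlation), with the largest falls at -0.49 and -0.81.

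The 15 other lists did not pass in Primed2 against Primed1, with p from 0.202 for fibroblast genes to 0.87. Fibroblast genes were higher in 12 cases and lower in 7, naive genes higher in DNMT3L, KHDC1L, FGFR3 and HORMAD1 and lower in 9, and primed genes higher in ZIC5, SOX11, ZIC2 and SFRP1 and lower in CYTL1, DNMT3B, THY1, GPC4 and NLGN4X. UHRF1, DNMT3L and TET2 were higher and ZFP57 and DNMT3B lower among DNA methylation genes (median -0.01, test upward), and HEY1, TNC, VTCN1 and IGFBP5 higher and BAMBI, IGFBP3 and ISL1+LOC642366 lower among amnion genes (median 2.39, or 0.00 with bounds). WNT3, EOMES, HAND1, T and GSC were higher and LEFTY2, LEFTY1, NODAL, MIXL1 and CER1 lower among mesendoderm genes (median 0.05, mean -0.22), and FOS was higher with 6 lower among ERK targets. ENPEP, CDX2, GCM1 and LOC100130275+TFAP2A were higher among trophoblast genes and those lower included EPAS1 and CYP19A1 (median -0.02, mean 0.15), STK31, DAZL, MOV10L1 and HORMAD1 higher with 6 lower among germline genes, and SLC34A2 and ZNF280A higher and CCNA1, DPPA3 and DUXA lower (2 lower adjusted over the list alone) among cleavage-stage genes (median 0.00, mean 0.64). ARHGEF17, ANKRD1 and LOC728463+TGFB2 were higher and CRIM1, TEAD4 and F3 lower among YAP targets, TP53INP1 and BTG2 higher and SESN2 lower among p53 targets, SESN3 higher and SESN2 lower among AMPK genes, SOCS1 and CEBPD lower among STAT3 targets (median 0.06, mean -0.03), and C18orf56+CLUL1+ENOSF1+TYMS higher among S and G2/M genes.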

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

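The tests for Primed1-like cells at the POU5F1 share mixed with differentiated cells, residual primed cells, feeder RNA and zinc finger blocks were chosen only after the results were seen.

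The change against primed cells differed between AICAR1 and AICAR2, which share a treatment label, for 1323 genes, by a test of the difference itself (edgeR, 3 libraries against 3). Of the 68 genes named for AICAR against primed, 7 differed. IGFBP5, which binds insulin-like growth factors, stood 3.24 ± 0.44 higher in AICAR2 on the log2 scale and TRIM49 1.06 ± 0.12 higher, whereas ADSSL1, an enzyme of the purine nucleotide cycle, stood at -1.82 ± 0.33 and the stress gene TRIB3 at -1.05 ± 0.05. CER1 (0 counts in AICAR1, 34 in AICAR2), PTPRZ1 (0 and 11) and APOA1 (1 and 8) rested on few counts, and their fitted differences of 6.72, 5.12 and 2.86 are no bounds. Fibroblast genes had a median difference of 0.90, cleavage-stage genes 0.89, primed genes 0.41, core pluripotency genes 0.39 and S and G2/M genes 0.34, and these 5 lists lost their calls with an estimated correlation (adjusted p = 0.121, 0.113, 0.121, 0.519 and 0.388).

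Of 29 fibroblast genes 11 were called higher in AICAR2 than in AICAR1 (adjusted p = 0.121 for the list with an estimated correlation), such as COL3A1+MIR3606 (78.8 against 4.85 CPM), COL1A2 (31.5 against 3.40) and COL5A2 (5.49 against 1.24), and so was the cadherin CDH2. With every library thinned to the smallest total, 1071 of the 1323 calls (81.0%) were kept, above the bound of 75%. Unequal totals were thus not needed for most calls. Thinning keeps each gene's expected share of the counts and removes calls mainly through lost power, so it does not decide what set the groups apart. Residual primed cells are argued against. If the COL1A2 excess, 10.6% of its primed level, came from such cells, other genes high in primed cells would carry a like share. The 90th percentile over 38 of them was 1.38%, under the bound of 2.64%. Feeder fibroblast RNA stays open, since 10 of 17 fibroblast genes under 5 CPM in AICAR1 were called higher in AICAR2 (58.8%, exact interval 32.9 to 81.6% around a bound of 75%), and SPARC, an abundant fibroblast gene that these cells also express, stood at 658 and 616 CPM. A change within the H9 cells of AICAR2 also stays open and was not tested.

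Primed2 differed from Primed1 in 3815 genes, with POU5F1 at 410 and 1495 CPM and the neural genes SOX1 and MAP2 higher. After thinning 3442 of 3815 calls (90.2%) were kept, above the bound of 75%, so unequal totals were not needed for most calls. Thinning removes calls mainly through lost power and does not decide what set the groups apart. Primed1-like cells at the share that POU5F1 gives, 0.275, mixed with differentiated cells are argued against as the whole cause. Such a mixture keeps every Primed1 gene at that share or above, but 139 of 9343 genes at 10 CPM or more in Primed1 lay below it (one-sided z test, adjusted p < 0.05, against a bound of 10). Among the genes also at 10 CPM or more in each reset group, ZNF253, PUS7L, PSMD5, MT1H and CSRP1 lay below 10% of that share. The count of 139 is approximate, because the ± values that the z test used are too small for genes with few counts. The error of POU5F1 is also shared by all of its tests. A smaller share beside cells that keep POU5F1, or a mixture together with other differences, stays open. A batch, another subline or a wrong label stays open and was not tested, and no biological explanation was tested.

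Zinc finger genes were among the largest rises in the 3 comparisons with primed cells, and were counted for that reason, without a test of enrichment: of 466, 136 were called higher and 57 lower in AICAR (29.2% higher, against 16.9% of other genes), 152 and 63 in NK2 (32.6% against 17.8%) and 151 and 58 in 5iLA (32.4% against 17.5%). Neighbouring zinc finger genes may move as blocks, up or down: clusters held 30.9, 27.8 and 27.8% of the spread of log2 fold changes over 292 genes in 29 clusters, against 9.26, 9.25 and 9.25% when shuffled, with p = 0.0001, the smallest that 10000 permutations can give. In the chromosome 19 cluster from ZNF101 to ZNF254, 22 of 34 members were higher in AICAR, 19 in NK2 and 20 in 5iLA. The zinc finger counts and cluster shares rest on the mean of both primed groups and were not repeated against Primed1 alone. A low level in Primed2 alone can therefore count as a rise. ZNF253, in this cluster, was called higher in all 3 comparisons. It stood at 21.2 CPM in Primed1, 0.148 in Primed2, 20.7 in AICAR1, 26.2 in AICAR2, 25.6 in NK2 and 23.7 in 5iLA. How many other zinc finger genes behave so was not counted. In the chromosome 3 cluster from ZNF445 to ZNF501, with 7 members, 2 were higher and 4 lower in AICAR, 1 and 4 in NK2, and 2 and 2 in 5iLA. Reads shared between these paralogs stay open, since the files hold no reads to test this with, although only uniquely mapped reads were counted. No biological explanation was tested.

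For 5 comparisons a share under 0.05 of the splits of the same libraries, fitted as 2 groups, gave as many called genes. This would exclude chance as the source of the group differences only if libraries were exchangeable. Libraries of a group resemble each other (consensus correlation 0.872), so they are not, and chance at the level of groups cannot be excluded. With whole groups as units each of these comparisons has 3 splits, too few for a share under 0.05. For AICAR against primed 1 of 100 splits, the real one, gave as many genes (6159, highest other 232), for NK2 against primed 1 of 84 (6476, highest other 2436) and for 5iLA against primed 1 of 84 (6356, highest other 2359). For AICAR against 5iLA it was 1 of 84 (1010, highest other 869). For AICAR against NK2 it was 2 of 84, since the split that set AICAR2 against AICAR1 and NK2 gave 1277 genes and the real one 926, which points to a structure of the samples: AICAR1 alone differed from NK2 in 875 genes and AICAR2 alone in 2360. For AICAR2 against AICAR1 (1108, highest other 0) and Primed2 against Primed1 (3709, highest other 0) the real split was 1 of 10, too few splits for a share under 0.05.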

How the results depend on the processing

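Library totals alone and thinning to the smallest total were alternatives chosen only after the data were seen. Of the values for named genes under alternatives other than leaving out a library, 3040 kept their direction and their side of the threshold, 44 lost their call, 6 gained one and 1 reversed. For single lists 1641 kept both, 81 lost their call, 45 gained one and 1 reversed. Leaving out 1 library at a time, 2332 values of named genes kept both and 8 lost their call, and for lists 1526 kept both, 2 lost their call and 32 gained one. Results that were not called changed sign in 114 cases (95 lists and 19 genes).

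Counts of called genes in AICAR, NK2 and 5iLA against primed, AICAR against NK2 and 5iLA, AICAR2 against AICAR1 and Primed2 against Primed1 were 13836, 13390, 13470, 8668, 8446, 8031 and 11276 with no fold threshold, which by construction lets small changes through. They were 4339, 4429, 4349, 254, 317, 216 and 1788 with limma on log2(RPKM + 1), which changed the unit, the scaling and the test together. With DESeq2 they were 7101, 7110, 7030, 1420, 1431, 1308 and 3764. With replicate number as a block they were 7077, 7119, 7045, 1432, 1448, 1314 and 3820, and the block ended no call of a named gene. The numbers pair nothing visible: over 45 pairings of groups and numbers, 2 correlations of residuals were over 0.1 (range -0.0749 to 0.175), and 9 of 18 libraries matched best with their own number. With group as a random block AICAR against primed had 4609 genes (consensus correlation 0.872). AICAR against NK2 had 875 genes and 2 lists with AICAR1 alone and 2360 genes with AICAR2 alone, and the cause was not tested.

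Leaving out 1 library gave 7190 to 7322, 7209 to 7263, 7146 to 7207, 1354 to 1446, 1362 to 1483, 1247 to 1309 and 3704 to 3961 genes in the same order. It gave 14 to 16, 12 to 13, 13 to 16, 9 to 11, 10 to 13, 5 to 7 and 10 to 11 lists. Each fit without a library applied the low-count filter anew and tested 15852 to 15984 genes instead of 15645. Shifts in these counts and lists therefore mix a looser filter with the effect of the library. With an estimated correlation the number of lists called was 4, 4, 4, 0, 2, 0 and 2, since that test allows for genes of a list moving together. Where camera with an estimated correlation gave 0, it had 5 and 3 lists at an unadjusted p under 0.05, and fry called 22 and 22. NANOG in NK2 reversed against Primed1 alone (-0.18, adjusted p = 0.318, against at most 0.00139 under every other alternative run), where NANOG was higher than in Primed2. S and G2/M genes in AICAR against 5iLA reversed with AICAR1 alone (median 0.0035 with the test downward, adjusted p = 0.548), and the cause was not tested.

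Genes called higher in AICAR and NK2 numbered 5428 with no fold threshold and 1300 on log2(RPKM + 1), and those called lower 6433 and 2340. For AICAR and 5iLA they were 5501 and 1305 higher, and 6467 and 2340 lower. Leaving out 1 library gave 2306 to 2499 higher and 3586 to 3801 lower with NK2, and 2277 to 2487 and 3605 to 3816 with 5iLA. The correlation with the NK2 change was 0.910 with no low-count filter, 0.914 with AICAR2 alone, 0.811 with AICAR against Primed1 and NK2 against Primed2, and 0.824 with these references exchanged. With the 5iLA change it was 0.909, 0.926, 0.811 and 0.825, and 0.938 to 0.947 without 1 library. The AICAR change as a share of the NK2 change was 0.745 and 0.880 with the split references. As a share of the 5iLA change it was 0.759 and 0.888 with them, 0.936 with no low-count filter, 0.973 on log2(RPKM + 1), 0.958 against Primed2 alone and 0.939 to 0.954 without 1 library. Split references carry the difference between Primed1 and Primed2 into 1 side only, and the cause of the other shifts was not tested. A pseudocount alternative on RPKM alone was not run because counts were given.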

Other observations

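The genes of this part were chosen only after their values were seen, and no test of an explanation was run here. The directions of called genes were the same under RLE and library total scaling, and B2M in AICAR, which was not called, turned to -0.06 with library totals.

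HLA-C, which presents peptides to T cells, fell by 2.70 ± 0.07 on the log2 scale in AICAR, 2.06 ± 0.09 in NK2 and 1.07 ± 0.08 in 5iLA against primed (81.5 CPM in Primed1, 42.9 in Primed2 and 28.2 in 5iLA), and CD74, a chaperone of class II molecules, by 4.63 ± 0.13, 2.58 ± 0.14 and 2.93 ± 0.14. B2M, the common light chain, stood at 0.08, 0.59 and 0.75 and HLA-E at -0.07, 0.56 and 0.14, none called. NLRC5 went the other way and rose by 1.45 ± 0.20, 1.32 ± 0.25 and 4.11 ± 0.18. Of the 11 antigen presentation genes picked, 8 fell in AICAR, 8 in NK2 and 6 in 5iLA, and 1 rose in each. HLA genes are polymorphic and share sequence, so their levels are uncertain.

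Of genes known from blood cells, picked because they rose, CD53 rose by 9.09 ± 0.12, 9.50 ± 0.12 and 8.80 ± 0.13 in AICAR, NK2 and 5iLA, BIN2 by 8.80 ± 0.17, 9.59 ± 0.18 and 9.13 ± 0.19, SPIC by 10.42 ± 0.16, 9.71 ± 0.19 and 9.71 ± 0.19, and HCLS1 by 5.95 ± 0.09, 7.07 ± 0.09 and 7.06 ± 0.09. Over the primed libraries CD53 had 16 counts, BIN2 6 and SPIC 6, so their ± values are too small. LCP1, an actin-bundling protein, went from 14.5 CPM in Primed1 and 2.01 in Primed2 to 1474 in AICAR1, 1255 in AICAR2, 1736 in NK2 and 1642 in 5iLA. Metallothioneins, which bind zinc and copper, were lower in Primed2 than in Primed1 for 7 of 7 genes (log2 fold change -6.47 to -1.79) and higher in AICAR2 than in AICAR1 for 7 of 7 (1.14 to 1.85). MT1G stood at 72.5 CPM in Primed1, 2.25 in Primed2, 107 in AICAR1, 266 in AICAR2, 71.5 in NK2 and 108 in 5iLA. The MT1 genes share sequence.

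Of the 5 genes picked for a level near 0 in Primed2 and at least 10 CPM in each other group, PSMD5, a proteasome chaperone, stood at 38.1 CPM in Primed1, 0.326 in Primed2, 52.0 in AICAR1, 53.4 in AICAR2, 69.2 in NK2 and 49.7 in 5iLA, and ZNF253 at 21.2, 0.148, 20.7, 26.2, 25.6 and 23.7. Of the neighbouring genes HHLA1 and OC90, HHLA1 stood at 63.8, 7.03, 0.251, 4.78, 39.2 and 34.7 CPM in the same order and OC90 at 1.52, 0.349, 0.0455, 0.582, 6.60 and 7.23.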
